A study of Mus musculus with 8 samples.

How the data were processed

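Gene expression was measured by RNA sequencing in hearts of adult FVB/N mice, an inbred strain often used to make transgenic lines. Per the labels, the 8 libraries came from 8 male mice at 3 months of age, 4 non-transgenic (hearts A, B, D and E) and 4 carrying a FASTKD1 transgene (hearts A, B, C and E). The series title calls the transgene cardiac-specific. Per the labels' protocols, RNA was taken up in Trizol and libraries were made with a TruSeq kit; whether the kit marks strand was not given in the sources used here. Each library was treated as 1 animal, since the titles give each heart its own letter within a group.

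The deposited values are whole-number counts per Ensembl gene, 1 library per file and not normalized. Per the submitters' processing notes, cutadapt 1.15 and TopHat2 were used with the builds GRCm38 and mm10, which are 2 names for the same mouse assembly. The read counter and the annotation release were not given in the sources used here. The deposited counts cover 13227 genes in each of the 8 libraries, and the second-highest CPM of every gene was at least 1.003. Genes that did not reach about 1 CPM in at least 2 libraries were therefore not analysed here. Symbols and coordinates were taken from GENCODE M21 on GRCm38; 12 identifiers had no entry there and kept their identifier.

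Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr by group, which kept 13226 genes, TMM scaling, and the quasi-likelihood F test (glmQLFit, glmQLFTest) of transgenic against non-transgenic hearts, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. No block was used, since nothing in the labels says that a letter shared by both groups pairs animals. CPM values use the TMM library sizes, and logarithms of single libraries use a prior count of 2. Every adjusted p for a gene comes from this edgeR test unless another tool is named. The SE of a log2 fold change was worked back from the same test, as the absolute log2 fold change divided by the square root of F. Counting intervals and limits are at the 95% level and cover counting error only. Single measures per library were compared with an exact permutation test over the 70 arrangements of the 8 libraries, two-sided, for which the smallest p is 0.0286.

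A set of 50 gene lists (pathways, complexes, markers of cell types a heart sample could hold) was fixed before the data were examined. The 48 lists with 3 or more tested members were tested with camera at a preset correlation of 0.01 between genes, which compares a list with all other genes, with Benjamini-Hochberg adjustment over the lists. Beside it stand camera with a correlation estimated from the data and fry, which asks whether a list's genes move on balance in one direction. For each list, the members past the threshold were counted over all genes and with adjustment over the list alone.

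The named genes were also fixed by rule before the data were examined: Fastkd1; among genes past the threshold with an average log2 CPM of at least 0, no overlap between groups and a proper symbol, the 12 with the largest rise, the 12 with the largest fall and the 6 with the smallest p; up to 4 members of each list with the smallest p; and all members of the FASTK family and the mitochondrially encoded mRNAs. Other genes named below were chosen after their values were seen: members of the integrated stress response list beyond its first 4, the atrial genes Myl4 and Myl7, Nppa, Nppb, Myh7, the X-linked genes and the letter-split genes named among the additional observations, Ptprt, Xpot, the aminoacyl-tRNA synthetases, the transporters Slc3a2, Slc38a1 and Slc6a9, and the neighbours of Vmn2r3.

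The fit was tested on simulated counts for 13226 genes with the means and library sizes of these 8 libraries and 230 changed genes, 30 of them a list raised 1.5-fold. In that simulated comparison of transgenic with non-transgenic hearts, it recovered 22% of 50 genes changed 1.5-fold, 80.0% of 50 changed 2-fold, 98.0% of 50 changed 4-fold and 100% of 50 changed 8-fold. Of the 30 genes of the raised list it called 8. Of its 165 calls, 7 were false (4.24%), and camera called the raised list (adjusted p = 2.97e-22) and 0 of 50 lists without change. The simulated genes were drawn independently of each other. The simulation therefore does not test camera on lists whose genes vary together, as in these hearts (estimated correlation 0.84 for complex I subunit genes). Alternatives covered other scalings, DESeq2 1.42.0, limma 3.58.1 (voom, with and without sample weights), the low-count filter, the threshold, a test against a 1.2-fold change, leaving out each library, a block on title letters and 1 surrogate variable from sva 3.50.0. The block compares genotypes within letters A, B and E only, since C and D occur in a single group each.

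Reads that also match a near-identical copy cannot be assigned with certainty from a count per gene, which applies here to Hspa1a with Hspa1b, Hba-a1 with its copy, and Rps4l. In the annotation, Ddit3 overlaps Mars, Atf5 overlaps Nup62 and Il4i1, and Gpr22 overlaps Cog5, each on the opposite strand; a further overlap is not reported here. Without strand information reads of such pairs could not be separated, and these genes are uncertain to that extent.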

Results

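The series profiled hearts of mice that overexpress FASTKD1, a mitochondrial RNA-binding protein of the FASTK family, beside hearts without the transgene. Total counts per library ran from 45802079 to 50830215 in the 4 non-transgenic hearts and from 44584359 to 55769859 in the 4 transgenic hearts, and their means did not differ beyond the spread between hearts (exact permutation p = 0.914). The 11 mitochondrially encoded genes analysed here took 23.8% ± 5.02 of counts in non-transgenic and 24.0% ± 2.19 in transgenic hearts (SD, n = 4 each; exact permutation p = 0.943). Pairs of libraries within a group correlated across genes at r = 0.963 to 0.993, where genes are not independent replicates, and no pair was close enough to be repeats of 1 library (chi-square per degree of freedom of at least 19.7). The first principal component held 35.4% of the variance, with non-transgenic hearts B and A at -44.5 and -23.9, the transgenic hearts at 4.57 to 23.8, and non-transgenic hearts D and E at 5.47 and -5.55.

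Fastkd1 (ENSMUSG00000027086; GRCm38 chromosome 2, 69686815 to 69713516, minus strand) reached 9932 ± 1162 CPM in transgenic hearts against 70.5 ± 80.9 CPM in non-transgenic hearts (SD, n = 4 each). The log2 fold change was 7.14 (SE 0.75, edgeR adjusted p = 0.000684), all 4 transgenic hearts lay above all 4 non-transgenic hearts, and the exact permutation test of log2 CPM gave its smallest possible p of 0.0286. The transgenic hearts had 10030 (A), 9341 (B), 8845 (C) and 11520 (E) CPM, between 0.938% and 1.2% of all counts. Non-transgenic hearts A, B and E had 26.3, 30.2 and 33.8 CPM. The heart labelled non-transgenic D had 192 CPM, from 10594 counts, and without it the log2 fold change was 8.36 (SE 0.18). Heart D, labelled male like the others, also had 0 counts of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together, where the other libraries had 10372 to 15914; its direction in each comparison below is that of the library labelled non-transgenic.

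**Figure D1:**
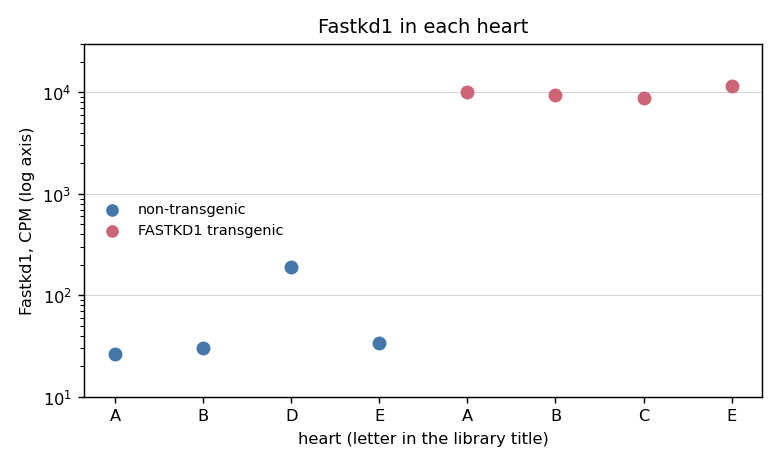
Fastkd1 in CPM (log axis) in each of the 8 hearts, 1 point per library, with non-transgenic hearts in blue and FASTKD1 transgenic hearts in red. The transgenic hearts lie between 8845 and 11520 CPM, and non-transgenic heart D at 192 CPM lies above the other non-transgenic hearts at 26.3 to 33.8 CPM.

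The other members of the FASTK family showed no such difference. Of the 6 tested members only Fastkd1 rose, over all genes and adjusted over the list alone. The log2 fold changes were -0.03 for Fastk, -0.24 for Fastkd2, -0.21 for Fastkd3, -0.10 for Fastkd5 and 0.00 for Tbrg4, with edgeR adjusted p from 0.517 to 0.996, and the set test gave an adjusted p of 0.357.

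In the comparison of transgenic with non-transgenic hearts, Mthfd2, a mitochondrial enzyme of folate metabolism, rose from 2.12 ± 0.541 to 127 ± 25.9 CPM (SD, n = 4 each), and Asns, which makes asparagine, from 2.52 ± 0.471 to 64.7 ± 10.8 CPM. The hormone gene Fgf21 rose from 0.0730 ± 0.0468 to 9.34 ± 2.69 CPM. Fewer genes fell and by less; among them were Lpl, the lipase that releases fatty acids from circulating triglyceride, and Tcap, a protein of the sarcomere Z-disc. Of 13226 tested genes, 133 rose and 32 fell (edgeR adjusted p under 0.05), 85 and 11 of them by at least 2-fold, while 1421 had an unadjusted p under 0.05.

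Of the genes that rose, 128 were protein coding, and of those that fell, 23. All 165 had no overlap between the groups, as had 976 of all tested genes, where chance gives 2.86% of genes. The count of genes that fell depended on single libraries: it was 10 without non-transgenic heart A, 50 without B, 72 without D, 9 without transgenic heart B and 14 without transgenic heart C. Without both non-transgenic heart D and transgenic heart A, a choice made after seeing the data, 170 genes rose and 106 fell. DESeq2 called 249 higher and 159 lower, and 148 of the 165 genes were among those called without hearts D and A.

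Some of the genes with the largest rises had almost no counts in non-transgenic hearts. Vmn2r3, a vomeronasal receptor gene (ENSMUSG00000091572; chromosome 3, 64257215 to 64289709, minus strand), had 2 counts over the non-transgenic hearts and 5204 over the transgenic hearts, a ratio of 2452 with a counting interval of 678.5 to 20250 (edgeR adjusted p = 5.55e-07). Adm2, which encodes a peptide of the calcitonin family, had 0 and 425 counts, a ratio with a lower counting limit of 108.1 (edgeR adjusted p = 0.000886). Soat2, an enzyme that esterifies cholesterol, rose by 7.41 on the log2 scale (SE 0.42), Ostn, which encodes the secreted peptide musclin, by 7.34 (SE 0.34), Fgf21 by 6.94 (SE 0.37) and the cationic amino acid transporter Slc7a3 by 6.50 (SE 0.54). The next were Mthfd2 at 5.90 (SE 0.23), the teneurin gene Tenm4 at 5.11 (SE 0.36), Cdsn, known from skin cell adhesion, at 4.95 (SE 0.32), Asns at 4.68 (SE 0.18) and the transcription factor gene Tfcp2l1 at 4.31 (SE 0.23). The pseudokinase gene Trib3 (4.01, SE 0.16) and Phgdh, the first enzyme of serine synthesis (4.22, SE 0.17), were among the 6 genes with the smallest p. Apart from Adm2, these edgeR adjusted p lay between 5.55e-07 and 0.000129, and all 12 of the largest rises kept their call when any one library was left out.

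Among the 12 largest falls, Tmem150c fell by 1.32 on the log2 scale (SE 0.20), the potassium channel subunit gene Kcnv2 by 1.17 (SE 0.17), the carboxylesterase gene Ces1d by 1.13 (SE 0.22), Cep128, a centriole protein gene, by 1.09 (SE 0.16) and the tropomodulin gene Tmod4 by 1.02 (SE 0.17). Ano10 went from 94.5 ± 9.26 to 48.4 ± 2.09 CPM (SD, n = 4 each; edgeR adjusted p = 0.000333), and the orphan receptor gene Gpr22 from 80.5 ± 22 to 41.6 ± 4.96 CPM (edgeR adjusted p = 0.0324). Efnb3 fell by 0.82, the slow skeletal troponin gene Tnnt1 by 0.66, P3h4 by 0.62, Dglucy by 0.59 and Lrrc15 by 0.54. Of these 12, Ano10, Efnb3, Kcnv2, Tmem150c and Cep128 kept their call when any one library was left out, and 7 lost it in at least 1 such set; Cep128 lost its call with a block on title letters (edgeR adjusted p = 0.0517).

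The integrated stress response list, genes induced through the transcription factors ATF4 and CHOP, rose in most members. Of 28 tested members, 21 rose, 0 fell and 7 did not pass; adjusted over the list alone, 26 rose. The median log2 fold change was 2.12, the set test had an adjusted p of 2.08e-245, and the adjusted p = 0.000809 with an estimated correlation. Besides Fgf21, Mthfd2, Asns, Phgdh and Trib3, the amino acid transporter gene Slc7a5 rose by 3.53 (SE 0.18), the glutathione-degrading enzyme gene Chac1 by 4.0 (SE 0.26), the cytokine gene Gdf15 by 3.11 (SE 0.33), Atf5 by 2.79 (SE 0.20), Atf4 itself by 1.29 (SE 0.12) and Ddit3, which encodes CHOP, by 0.92 (SE 0.12). Serine and proline synthesis genes were among them, with Psat1 at 2.17, Pycr1 at 2.86 and Aldh18a1 at 2.36. Averaged over the 21 genes that rose, log2 CPM was 4.40 in transgenic heart A and 4.67 to 4.83 in transgenic hearts B, C and E, against 1.54 to 1.98 in the non-transgenic hearts.

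**Figure D2:**
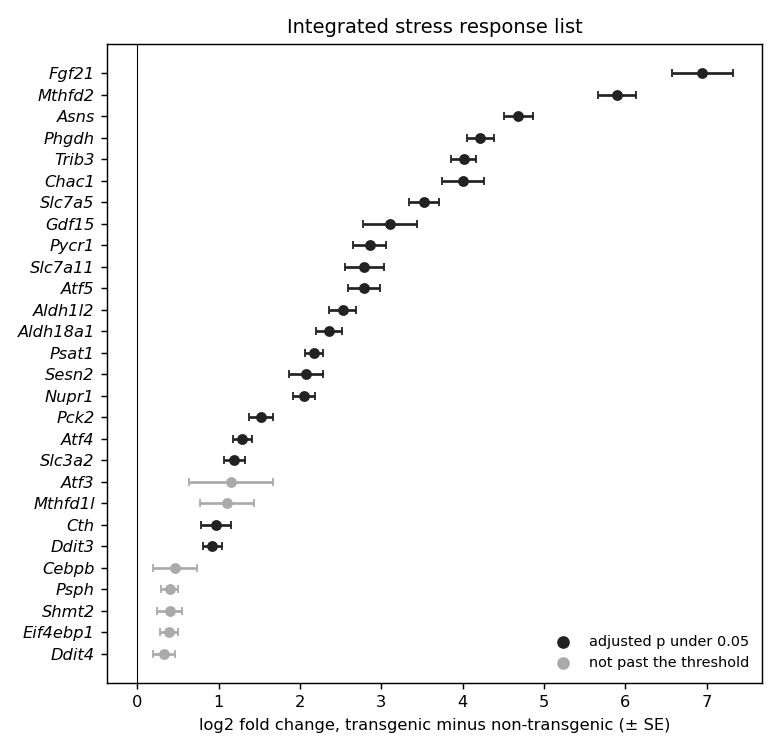
Log2 fold change of each tested gene of the integrated stress response list, transgenic minus non-transgenic hearts, with bars of 1 SE worked back from the edgeR F test (n = 4 hearts per group). The 21 genes in black had an adjusted p under 0.05 and the 7 in grey did not; Fgf21 at 6.94 and Mthfd2 at 5.90 lie at the top.

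Of 16 tested p53 targets, 3 rose, 0 fell and 13 did not pass, with 4 that rose adjusted over the list alone (set test adjusted p = 1.25e-09; adjusted p = 0.0384 with an estimated correlation). The 3 were the cell cycle inhibitor gene Cdkn1a at 2.1 (SE 0.18), Sesn2 at 2.07 (SE 0.21), which the stress response list also holds, and Gadd45a at 1.62 (SE 0.17). The median of the list was 0.29. Of 23 cell cycle genes, Cdkn1a and Ccnd2 (1.33, SE 0.18) rose, 0 fell, and the set test adjusted p was 0.864. Of 26 immediate early genes, Myc rose, at 2.15 (SE 0.20; set test adjusted p = 0.771).

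Chaperone and protein quality genes rose in part. Of 19 heat shock chaperone genes, Hspa1a (2.67, SE 0.33), Hspa1b (1.85, SE 0.33) and Hsp90aa1 (0.68, SE 0.12) rose, 0 fell and 16 did not pass, with 5 that rose adjusted over the list alone. The set test adjusted p was 8.41e-05, and the adjusted p = 0.498 with an estimated correlation. Of 20 mitochondrial protein quality control genes, 2 rose and 18 did not pass: the protease gene Lonp1, from 145 ± 23.9 to 301 ± 55.5 CPM, and the chaperone gene Hspa9, from 933 ± 79.0 to 1331 ± 76.1 CPM (SD, n = 4 each; set test adjusted p = 0.195). The log2 fold changes of the chaperonin genes Hspd1 and Hspe1 were 0.28 and 0.25 (edgeR adjusted p = 0.417 and 0.471). Of 21 endoplasmic reticulum stress genes, the sensor gene Atf6 (0.84, SE 0.08) and Herpud1 (0.42, SE 0.09) rose, 19 did not pass, and 5 rose adjusted over the list alone (set test adjusted p = 0.182). Of 30 antioxidant genes, the cystine transporter gene Slc7a11 (2.79, SE 0.24), Srxn1 (0.71, SE 0.08) and the metallothionein gene Mt2 (1.26, SE 0.21) rose, 27 did not pass, and 7 rose adjusted over the list alone (set test adjusted p = 0.0649). Hspa9, Hsp90aa1, Herpud1, Hspa1b and Mt2 lost their call when any of several single libraries was left out, with edgeR adjusted p up to 0.164, 0.106, 0.236, 0.1045 and 0.0764. Lonp1 and Srxn1 lost theirs with a block on title letters (0.102 and 0.0551), as did Hspa9, Hsp90aa1, Herpud1 and Mt2. Herpud1 also lost it with DESeq2 size factors, upper quartile scaling and the stricter low-count filter. Hspa1b also lost it with limma-voom, with and without sample weights.

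Contractile genes were lower as a list, with 1 member past the threshold. Of 26 sarcomere genes, Tcap fell, from 1024 ± 76.0 to 723 ± 48.1 CPM (SD, n = 4 each; edgeR adjusted p = 0.0319), and 25 did not pass, while 12 fell adjusted over the list alone. The median was -0.28, the set test adjusted p was 1.65e-08, the adjusted p = 0.210 with an estimated correlation, and fry gave 0.0285. Tnnt2 and Myl2 had log2 fold changes of -0.39 and -0.55 (edgeR adjusted p = 0.142 and 0.158). Of 18 calcium handling genes, Hrc, a calcium-binding protein gene of the sarcoplasmic reticulum, fell by 0.48 (SE 0.09), 17 did not pass, and 2 fell adjusted over the list alone. That list's set test adjusted p was 0.0253, the adjusted p = 0.501 with an estimated correlation, and its median was -0.13 beside a mean of 0.01. It passed neither without transgenic heart A (0.0523) nor without transgenic heart E (0.0641). Tcap lost its call without non-transgenic heart A or any one transgenic heart, and Hrc without non-transgenic heart A or E or any one transgenic heart, with edgeR adjusted p of 0.0703 to 0.176. Both also lost it with a block on title letters, and Tcap with library totals only. Of 29 ion channel and gap junction genes, 0 rose, 0 fell and 1 fell adjusted over the list alone (set test adjusted p = 0.0649).

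Of 22 fetal and hypertrophic program genes, Uchl1 (1.11, SE 0.16) and Tgfb2 (0.71, SE 0.14) rose, 0 fell and 20 did not pass; adjusted over the list alone, 7 rose and 3 fell. The median was 0.36, the set test adjusted p was 0.000600, the adjusted p = 0.210 with an estimated correlation, and fry gave an adjusted p of 0.0353. Uchl1 lost its call with a block on title letters (edgeR adjusted p = 0.0638), and Tgfb2 without any one library except non-transgenic heart D and transgenic heart A (0.0684 to 0.164). Tgfb2 also lost its call with library totals only. The natriuretic peptide genes Nppa and Nppb had log2 fold changes of 1.47 (SE 1.22) and -0.39 (SE 0.14), and the beta myosin gene Myh7 -0.38 (SE 0.13), with edgeR adjusted p of 0.755, 0.350 and 0.297. Nppa stood at 858 CPM in transgenic heart A, 241 CPM in non-transgenic heart D and 12.9 to 52.8 CPM in the other 6 hearts. The atrial light chain gene Myl4 was likewise at 1289 CPM in transgenic heart A, 175 CPM in non-transgenic heart D and 104 CPM in transgenic heart B, against 1.05 to 17.0 CPM elsewhere. Of 14 atrial tissue markers, 0 rose or fell (median 0.74; set test adjusted p = 0.365), and of 12 conduction system markers likewise 0 (0.744). Of 39 extracellular matrix genes, Tgfb2 rose, with the same losses, and 38 did not pass, with 2 that rose adjusted over the list alone (set test adjusted p = 0.0219; adjusted p = 0.771 with an estimated correlation). The matrix list did not pass without non-transgenic heart B (0.460), without non-transgenic heart E (0.0710) or without transgenic heart A (0.119), nor with library totals only (0.0907) or with 1 surrogate variable (0.141).

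Nuclear genes of mitochondrial energy metabolism were lower as lists, and of their members only Lpl passed the test. Of 38 genes of fatty acid oxidation and uptake, Lpl fell, from 5109 ± 596 to 3533 ± 182 CPM (SD, n = 4 each; edgeR adjusted p = 0.0393), 37 did not pass, and 4 fell adjusted over the list alone (median -0.34; set test adjusted p = 1.01e-08; adjusted p = 0.687 with an estimated correlation). Of 36 complex I subunit genes, 0 rose and 0 fell (median -0.30; set test adjusted p = 2.94e-11; adjusted p = 0.687 with an estimated correlation), and of 42 genes of complexes II to V also 0, with 1 that rose adjusted over the list alone (median -0.24; set test adjusted p = 2.13e-07; adjusted p = 0.687 with an estimated correlation). The set test was also passed by 77 mitochondrial ribosome genes (median -0.12; 0.00196, and 0.787 with an estimated correlation), 18 tricarboxylic acid cycle genes (median -0.14; 0.00139 and 0.687) and 19 genes of ketone and branched-chain amino acid use (median -0.20; 0.00256 and 0.687). Mean log2 CPM of complex I was 8.24, 8.30 and 7.92 in non-transgenic hearts A, B and E, above the transgenic hearts at 7.71 to 7.86, and 7.77 in non-transgenic heart D (exact permutation p = 0.0857). For fatty acid genes it was 7.86, 7.97 and 7.74 in hearts A, B and E, 7.27 in heart D and 7.25 to 7.55 in transgenic hearts (exact permutation p = 0.143). Heart D was likewise the only non-transgenic heart not above every transgenic heart for complexes II to V, the tricarboxylic acid cycle and ketone and branched-chain amino acid use; for the mitochondrial ribosome heart E was not above them either. Without non-transgenic heart B, the mitochondrial ribosome list did not pass (0.0960), as with limma-voom sample weights (0.113), and Lpl lost its call without any one library except non-transgenic hearts B and D, with edgeR adjusted p of 0.0593 to 0.180. Lpl also lost its call with a block on title letters.

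**Figure D3:**
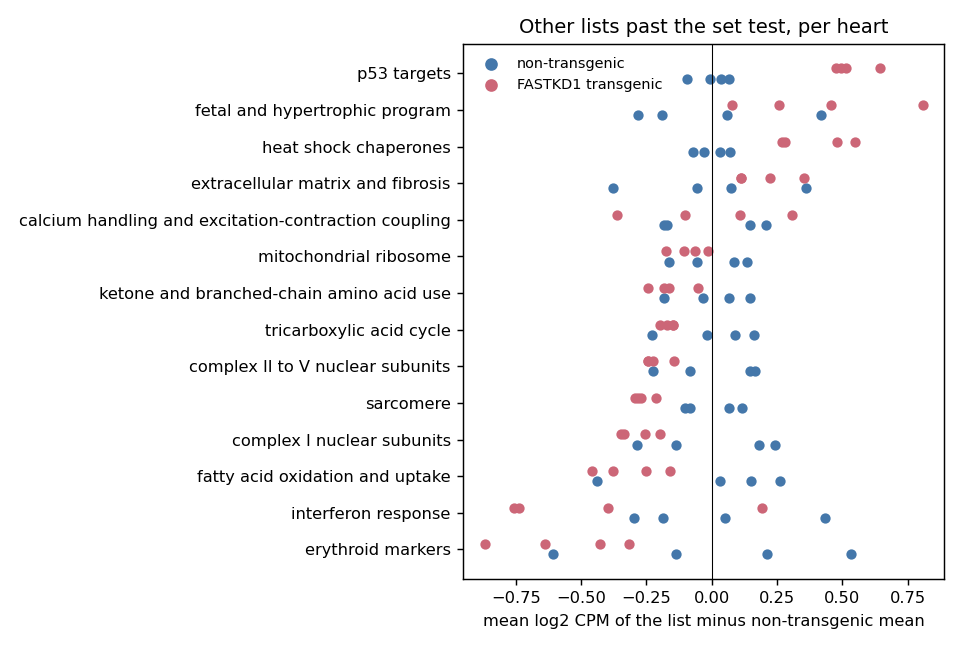
Mean log2 CPM of each list past the set test, other than the integrated stress response, minus the mean of the 4 non-transgenic hearts; each point is 1 heart, non-transgenic in blue and FASTKD1 transgenic in red. The groups do not overlap for p53 targets, heat shock chaperones and sarcomere genes (exact permutation p = 0.0286 each) and overlap for the remaining lists drawn.

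Other mitochondrial lists did not pass: 29 genes of mitochondrial RNA and DNA maintenance (set test adjusted p = 0.479), 23 of mitochondrial dynamics (0.121), 24 of mitophagy and autophagy (0.421), 23 of permeability transition and apoptosis (0.993) and 9 of mitochondrial calcium uptake (0.844), each with 0 members past the threshold. Of 27 glycolysis genes 0 passed; adjusted over the list alone, 1 rose and 3 fell (set test adjusted p = 0.0679). Of 77 cytosolic ribosome genes, only Rps4l, annotated as a transcribed processed pseudogene, rose (1.14, SE 0.18; edgeR adjusted p = 0.115 with a block on title letters; set test adjusted p = 0.0523), and of 19 glucocorticoid and fasting targets Cdkn1a and Mt2 rose (0.382).

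The mitochondrially encoded mRNAs, the transcripts that FASTK family proteins are known to act on, were tested for 7 of 13 genes; the rest, mt-Nd3 among them, were not analysed here. None of the 7 passed by edgeR (set test adjusted p = 0.969) or adjusted over the list alone, with log2 fold changes from -0.52 (SE 0.20) for mt-Co1 to 0.39 (SE 0.22) for mt-Nd5. As shares of the summed counts of the 11 mitochondrially encoded genes analysed here, a measure chosen after seeing the data, several transcripts did separate the groups. These shares add up to the whole, so a lower mt-Co1 share raises others, and they are not independent findings. The share of mt-Co1 was 32.4% ± 0.619 in non-transgenic and 24.2% ± 0.828 in transgenic hearts, and that of mt-Nd5 9.36% ± 0.537 and 13.2% ± 0.146. The share of mt-Nd1 was 13.2% ± 0.367 and 16.5% ± 0.153, and that of mt-Nd6 2.40% ± 0.0835 and 2.87% ± 0.114 (SD, n = 4 each). Each of these 4, and mt-Rnr1, mt-Tc and mt-Tp, had the smallest exact permutation p of 0.0286, or 0.0449 after Benjamini-Hochberg adjustment over 11 genes. The shares of mt-Nd2, mt-Nd4, mt-Cytb and mt-Rnr2 overlapped between the groups.

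**Figure D4:**
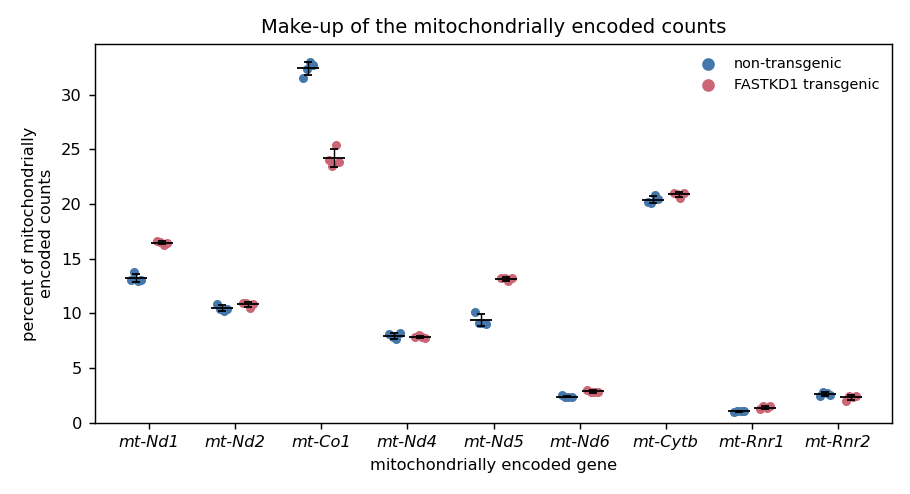
Share of each gene in the summed counts of the 11 mitochondrially encoded genes analysed in a heart, in percent, for 9 of them. Points are hearts (non-transgenic blue, FASTKD1 transgenic red), and bars give the mean ± SD of 4. The share of mt-Co1 is 32.4% in non-transgenic and 24.2% in transgenic hearts, and those of mt-Nd1 and mt-Nd5 are higher in transgenic hearts.

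Immune genes did not pass singly. Of 35 interferon response genes, 0 rose and 0 fell, all 35 had a negative log2 fold change, and the median was -0.38 (set test adjusted p = 7.48e-06; adjusted p = 0.687 with an estimated correlation). Their mean log2 CPM ran from 2.35 to 3.30 in transgenic hearts and from 2.81 to 3.54 in non-transgenic hearts (exact permutation p = 0.171). Of 24 cytokine and chemokine genes 0 passed (set test adjusted p = 0.215). Of 6 erythroid genes 0 passed over all genes and 4 fell adjusted over the list alone, with the globin gene Hbb-bs at -0.67 (SE 0.22); the set test adjusted p was 0.000372, and the adjusted p = 0.687 with an estimated correlation.

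Markers of other cells did not pass the set test. The adjusted p was 0.942 for fibroblasts, 0.199 for endothelium, 0.767 for endocardium and lymphatics, 0.863 for smooth muscle and pericytes, 0.0801 for macrophages, 0.0523 for T and NK cells, 0.230 for B cells, 0.498 for neutrophils and mast cells, 0.0511 for adipocytes, 0.748 for Schwann cells and neurons, 0.815 for epicardium and mesothelium, and 0.498 for skeletal muscle. Apart from Lpl, which the adipocyte list also holds, 0 of their members rose or fell. Adjusted over the list alone, 2 adipocyte genes fell, 1 smooth muscle gene rose, and 1 Schwann cell or neuronal gene rose and 1 fell. Few markers could be tested for T and NK cells (5 of 15), B cells (3 of 11), neutrophils and mast cells (4 of 14) and skeletal muscle (3 of 15). Over the alternatives, the adipocyte list passed in 8 of 23, T and NK cells in 8 of 22, macrophages in 5 of 23 and B cells in 1 of 23. The circadian clock list had 0 of 21 members past the threshold (0.767). The sex-linked list, tested for its Y-linked genes and not for Xist, had 0 of 4 (0.195). The lung and the thymus and lymph node lists had 1 tested member each, Hopx and Cd1d1, which did not pass over all genes, and were too short for a set test. In all, 15 of 48 lists passed the set test, 5 upward and 10 downward, and with an estimated correlation 2 did, the integrated stress response and p53 targets.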

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

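The tests on heart D other than that on X-linked genes, those on mitochondrial shares and those on Vmn2r3 were chosen only after the result was seen, as was the way in which the genes that fell were counted over other splits. Over 220 groups of 4 values, 16 held 1 heart far from the other 3, where chance gives about 11.

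In non-transgenic heart D, Fastkd1 stood at 192 CPM, against 26.3 to 33.8 CPM in the other 3, and the Y-linked genes Eif2s3y, Kdm5d and Uty stood at 0 CPM, against at least 71.1, 19.8 and 34.9 CPM. Transgenic heart RNA mixed into this library, at the 1.63% that Fastkd1 would need, predicts 68.5 counts (53 to 85) over 7 genes under 0.2 CPM in the other non-transgenic hearts, among them Ostn and Ptprt, and 17 were found; a male source, as all 4 transgenic hearts were by their Y-linked counts, would also bring 231.5 Y-linked counts, and 0 were found. The 7 genes were themselves narrowed down after values had been seen. A wider set of 12 genes had 520 counts, between the 377 of the highest other non-transgenic heart and the 659 that mixing predicts. A mislabelled transgenic heart is argued against by the 20 stress response genes that rose in the fit without heart D, whose median position in heart D was 9.75% of the way from the other non-transgenic hearts to the transgenic hearts (-3.53% to 30%). The X-linked genes Ddx3x, Eif2s3x, Kdm5c and Kdm6a escape X inactivation in mice. Their mean log2 CPM was 6.09 in heart D and 5.38 to 5.63 in the other 7 libraries, as tissue from a female mouse would give. Singly, Eif2s3x, Kdm5c and Kdm6a were highest in heart D, while Ddx3x was at 330 CPM there and 352 CPM in non-transgenic heart B. Xist, listed beside the Y-linked genes, was not among the genes analysed here. Whether the 8932 Fastkd1 counts above the level of the other hearts came from the endogenous gene, from transgene DNA or from an amplicon cannot be told apart, because counts per gene hold no read positions.

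The mitochondrially encoded counts had other proportions in transgenic hearts, with the mt-Co1 share lower by 8.24 percentage points in the group means. A trend with the mitochondrial share of a library is argued against by the non-transgenic hearts, whose mitochondrial shares spanned 11.5 points and whose mt-Co1 shares spanned 1.44 points. No single library carried the difference, since leaving out each in turn gave differences of -8.01 to -8.64 points. The log2 ratio of mt-Co1 to mt-Cytb differed by -0.46 and that of mt-Nd5 to mt-Cytb by 0.46 (exact permutation p = 0.0286 each, the smallest possible). The genotype and processing shared by all transgenic hearts stay open as untested explanations, and only 11 mitochondrially encoded genes were analysed here.

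Vmn2r3 was the only gene of its receptor family in the counts analysed here and was present almost only in transgenic hearts. Fastkd1 transgene reads assigned to it at a fixed rate would keep a fixed ratio to Fastkd1. The ratio ran from 0.1775% to 0.3317% between transgenic hearts, on 784 to 1550 Vmn2r3 counts, which argues against a fixed rate. Misassignment at a rate that varied between libraries cannot be told apart from Vmn2r3 RNA. Non-transgenic heart D, with 1 Vmn2r3 count, decides nothing, because its Fastkd1 counts need not be transgene RNA. A transgene insertion beside it, acting on this gene alone, cannot be told apart from induction by the transgene product: of the 5 tested genes starting within 1 Mb, 0 were higher and Gm34302 was lower (-1.23, edgeR adjusted p = 0.00866), but neighbours that are not higher exclude no effect on a single gene. Transgenic heart A, lowest of its group in Vmn2r3 with 784 counts against 1351 to 1550, also had the lowest mean of the stress response genes, a relation that 4 hearts are too few to test.

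In transgenic heart A, Nppa stood at 858 CPM against 17.4 to 50.6 CPM in the rest of its group and Myl4 at 1290 CPM against 1.46 to 104 CPM, Ces1d at 83.6 CPM against 45.8 to 48.6 CPM, Aldh18a1 at 32.0 CPM against 48.3 to 50.7 CPM, Hspa9 at 1220 CPM against 1350 to 1380 CPM, and the synthetase gene Yars at 39.0 CPM against 54.7 to 55.1 CPM. Among the other transgenic hearts, Myh7 stood at 946 CPM in E against 749 to 782 CPM, and Tcap at 652 CPM in C against 741 to 757 CPM. Among non-transgenic hearts, Myl4 stood at 175 CPM in D against 1.05 to 17.0 CPM, Lpl at 6000 CPM in B against 4740 to 4860 CPM, Tnnt1 at 9.08 CPM in E against 12.3 to 12.9 CPM, and the synthetase gene Iars at 68.9 CPM in A against 75.8 to 77.0 CPM.

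Over the 35 splits of the 8 libraries into 4 and 4, only the real one gave 165 differing genes or 133 in one direction. The highest other splits gave 63 and 62. For each count this is 1 of 35, the smallest value that 35 splits can give. Every other split placed transgenic hearts on each side, so the genotype difference could widen the spread there and lower the counts. The splits therefore cannot decide whether chance gave either count. For the 32 genes that fell, 2 of 35 splits gave as many in one direction (highest other 62), so chance was not excluded. That rule, chosen after the result was seen, sets the smaller direction of the real split against the larger direction of the others. By the smaller direction of each split, the way set before the data were examined, no other split gave more than 1. The larger direction is the less favourable reading. For the 15 lists past the set test, 26 of 35 splits gave as many (highest other 28), so this number alone does not set the groups apart. The split with 63 genes set hearts with the letters A and B against those with C, D and E, 2 transgenic and 2 non-transgenic on each side. It was singled out for having the most calls after the real split, and the meaning of the letters was not given. Whether it reflects a structure of the samples that crosses genotype was not tested.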

How the results depend on the processing

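Leaving out non-transgenic heart D with transgenic heart A, and a covariate for title letters A and B against C, D and E, were chosen after seeing the data; the other alternatives were planned. Fastkd1 kept its call throughout (log2 fold change 6.86 to 8.42), and 20 to 24 stress response genes rose in each setting with 0 that fell. Scaling moved the count little (164 to 168 differing genes) and the median log2 fold change by under 0.08, but with library totals only 137 of the 165 calls were shared. The counts of differing, higher and lower genes moved to 408, 249 and 159 with DESeq2, to 602, 366 and 236 with limma-voom sample weights, and to 314, 217 and 97 with 1 surrogate variable. Without hearts D and A, 276 genes differed and 106 were lower. Lower genes numbered 9 at an adjusted p under 0.01, 69 at 0.1, 11 against a 1.2-fold change and 69 with the letter covariate. Leaving out each library in turn gave 112 to 218 differing genes, 103 to 168 higher and 9 to 72 lower. Apart from the stricter and looser thresholds, the cause of these moves was not tested. Fewer libraries alone do not account for them, since 218 genes differed without non-transgenic heart B and 210 without D. A replicate block on title letters gave 124 differing genes and 21 lower. Letters C and D occur in a single group each, so this fit compared genotypes within letters A, B and E only. It was left with few degrees of freedom. Lonp1, Rps4l, Uchl1, Srxn1 and Cep128 lost their call only there (adjusted p = 0.102, 0.115, 0.0638, 0.0551 and 0.0517). So few shared letters cannot decide whether letters pair hearts: deviations correlated at 0.30 (A), -0.09 (B) and 0.36 (E). Transgenic hearts A and E correlated best with the non-transgenic heart of their own letter, and transgenic heart B with non-transgenic heart A (0.23). Lists past the set test fell from 15 to 2 with an estimated correlation and to 4 by fry, and numbered 16 to 20 without 1 library. The only reversed result was the immediate early gene list, downward with limma-voom sample weights (adjusted p = 0.00514; 0.00514 to 0.993 over its alternatives). Of 56 named genes past the threshold, 35 kept their call in every setting at 0.05 or 0.1; over 24 alternatives, named genes lost a call 151 times and gained one 145 times. The test against a 1.2-fold change gave no list value. In simulated counts of this depth, 22% of 1.5-fold changes were found, which limits what falls of that size can show.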

Other observations

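Cytosolic aminoacyl-tRNA synthetases, the enzymes that load amino acids on tRNA for protein synthesis outside mitochondria, rose in part. This group and its test were chosen only after the result was seen. Genes were sorted by symbol, and Gars and Kars, counted here as cytosolic, each also encode the mitochondrial enzyme. Of 20 tested genes, 9 rose, 0 fell and 11 did not pass (edgeR), with Gars at 1.35 (SE 0.10), Sars at 1.16 (SE 0.10), Iars at 0.90 (SE 0.11) and Nars at 0.84 (SE 0.13); the median over all 20 was 0.53 (camera p = 0.00462 with an estimated correlation, fry p = 0.000251, both unadjusted). The tRNA exporter gene Xpot rose by 1.24 (SE 0.09). Of 17 mitochondrial synthetase genes, which the nucleus also encodes, 0 rose and 0 fell (edgeR), with log2 fold changes from -0.23 to 0.14. The mean log2 CPM of the cytosolic minus the mitochondrial genes was 1.2 ± 0.072 in non-transgenic and 1.82 ± 0.078 in transgenic hearts (SD, n = 4 each; exact permutation p = 0.02857, the smallest possible), which argues against a rise shared by the 17 mitochondrial genes. The mitochondrial enzymes that Gars and Kars encode are not covered by it. The amino acid transporter genes Slc3a2 (1.19), Slc38a1 (2.1) and Slc6a9 (2.96) rose as well, with edgeR adjusted p of 0.000779, 0.0151 and 0.00174. A hypothesis that goes with this difference is that the response may raise mRNA of the cytosolic set and not of these 17 mitochondrial synthetase genes. It was found and tested on the same hearts, and only other transgenic hearts would test it. Charging of tRNA was not measured.

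Hearts with the letters C, D and E differed from those with A and B in 63 genes by edgeR, 62 of them higher in C, D and E, 28 protein coding, and 0 shared with the 165 genes that differed by genotype. Among them were the nuclear noncoding RNA genes Neat1 (1.08) and Firre (1.27), Leng8 (1.16) and Vegfa (0.89), and Txnip was lower (-0.74). With these letters as a covariate, 165 genes were higher and 69 lower in transgenic hearts.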
